A study of Danio rerio with 15 samples.

How the data were processed

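Each array carried total RNA from 10 pooled brains of zebrafish larvae kept singly in wells under constant light for 3 h with a compound or DMSO, per the labels' protocols. RNA was extracted with a micro-scale column kit and labelled with Cy3 by a low-input single-colour kit, per the labels' protocols. Per the submitters' processing notes the scans were read with Agilent Feature Extraction 12.0.3.1. The processed signal intensity of each spot, after background correction by that program, was taken as deposited, per the file headers. Another deposited table holds log2 values, which differ from the log2 processed signal by a constant per array to within 0.656 and were scaled to the array's 75th percentile, as the values themselves show. It served as an alternative.

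Of 45220 spots per array 43803 were not controls, and these made 43603 probes, with repeated spots averaged. Intensities were scaled to each array's 75th percentile, floored at 1 (64 scaled values) and log2-transformed. Probes were kept where the files mark them well above background on all 3 arrays of at least 1 group, which left 35765. Names came from a table of RefSeq accessions and symbols, which named 27276 probes (62.6%). The array's own coordinates refer to an older assembly and were not used. For the 7282 genes with several kept probes the brightest was used, so that 13021 named genes and 11294 unnamed probes were tested, 24315 in all. Probe sequences were not examined, so transcripts of near-identical genes may share a probe. The array has 1 probe for the orexin receptor gene hcrtr2, which was not kept.

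All 15 arrays were fitted together with 1 mean per group (limma 3.58.1 under R 4.3.3, with data.table, version 1.17.8, and jsonlite 2.0.0), with lmFit and eBayes without trend or robust options, two-sided. A transcript passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Errors are standard errors of the log2 difference. Where a gene was well above background on no array of a group, its level there was set to at least the lowest level marked well above background on each array, and the fold is given as at least that value. Lists were tested with camera at its preset correlation between genes of 0.01, adjusted over the 30 lists of pathway genes, brain cell types and other tissues, and again with a correlation estimated from the data, under which no list passed in any comparison. Members of a list were also adjusted over the list alone. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The blocks for scan session, the fit of session 2 alone, the random slide block the fit without 3 arrays with markers of other tissues, and the replicate block for HTC at 10 µM against imipramine were added afterwards.

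The rule names, per comparison, the 10 largest rises and 10 largest falls among genes with a symbol that passed with no overlap between groups, and up to 4 list members per direction that passed, or the 2 with the smallest p where none did. It also names a fixed set of genes in every comparison, and the 3 with the smallest p per direction where fewer than 5 passed. It gives 551 values, 318 of them past the threshold. The text prints 115 values, 2 of them from outside the rule. The printed genes were selected from the rule's after their values were seen, and their stability when single arrays were left out was known, so the printed set holds more stable calls than the rule's. The exceptions from outside the rule are fkbp5 and the unnamed probe A_15_P567777 in the imipramine comparison.

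Residuals from the group means were correlated between arrays of the same replicate number. For imipramine with DMSO these were 0.406, 0.527 and 0.349, and for HTC at 10 µM with DMSO 0.257, 0.538 and 0.325, all above the limit of 0.1 set for pairing, so the replicate block is given beside those results (75 and 197 transcripts). The scan sessions and slides came from the file headers. The 5 arrays of replicate 1 form session 1 and the other 10 session 2, on 6 slides, and the groups are unevenly spread over the slides. Replicates 2 and 3 of each HTC dose lie alone on a slide, and no DMSO array shares a slide with HTC at 100 µM. With the slide fixed, differences of an HTC group therefore rest on its replicate 1. For 100 µM that array is linked to DMSO only through other treatments.

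The scripts were tested on simulated data with 200 genes changed among 24315 units in 10 runs. At a log2 change of 1 the share recovered was 72.1% for suvorexant, 70.7% for imipramine, 71.3% and 72.4% for HTC at 10 µM and 100 µM, and 70.6% between the doses. At a log2 change of 0.5 it was 17.0%, 12.7%, 10.7%, 14.8% and 13.6% in the same order. False calls made up 4.99%, 5.53%, 5.05%, 4.41% and 4.91% of those made. The simulated values were independent between genes and arrays, without the correlations by replicate number or slide in the data. These shares may therefore not hold for the real arrays.

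The alternatives were quantile normalization, normexp background correction of the median signal with an offset of 50 (the mean signal is not given in the sources used here), the deposited log2 values, other filters on dim probes, the mean of a gene's probes or every probe singly, eBayes with trend and robust options, array weights, only the 2 groups compared, blocks for replicate and slide, an adjusted p under 0.1, a 1.5-fold minimum, a floor of 16, and each array left out in turn. Overlaps and correlations between comparisons were set beside simulated unchanged groups sharing simulated DMSO arrays, all drawn from the residuals of the real arrays. For overlaps the transcripts ranked highest were taken in the called number, whether or not they passed. Groups were also mixed, in every other split of the 6 arrays of a comparison, in 100 regroupings of all arrays and in 100 within replicate numbers.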

Results

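Transcript levels were measured on single-colour oligonucleotide arrays in brains dissected from zebrafish larvae at 8 dpf (days post fertilisation), after 3 h in a compound or in the solvent DMSO alone. Each array carried RNA from a pool of 10 brains. There were 5 groups of 3 arrays, which the labels describe as biological replicates: DMSO, suvorexant at 1 µM, imipramine at 1 µM, and 8β-(4'-hydroxytigloyloxy)costunolide (HTC) at 10 µM and at 100 µM. Suvorexant blocks the receptors of the wake-promoting neuropeptide orexin. Imipramine is a tricyclic antidepressant that inhibits the uptake of serotonin and noradrenaline, and HTC is a sesquiterpene lactone of the costunolide type. Between 34857 and 37174 probes per array (79.9% to 85.3%) were well above background, no spot was saturated. Arrays of one group correlated at 0.986 to 0.993 across probes. The first principal component held 35.1% of the variance and placed the arrays of HTC at 100 µM between 55.7 and 60.1, those of DMSO between -39.8 and -16.7, and imipramine replicate 1 at 20.2. All arrays of replicate 1 were scanned in session 1 and the other 10 in session 2. Of 24315 transcripts tested (13021 named genes and 11294 probes with no gene name), 3444 differed among the 5 groups in limma's F test at an adjusted p under 0.05, and 4519 did with the session as a block. That number was 2195 without HTC 100 µM replicate 2 and 1842 without HTC 100 µM replicate 3.

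**Figure D1:**
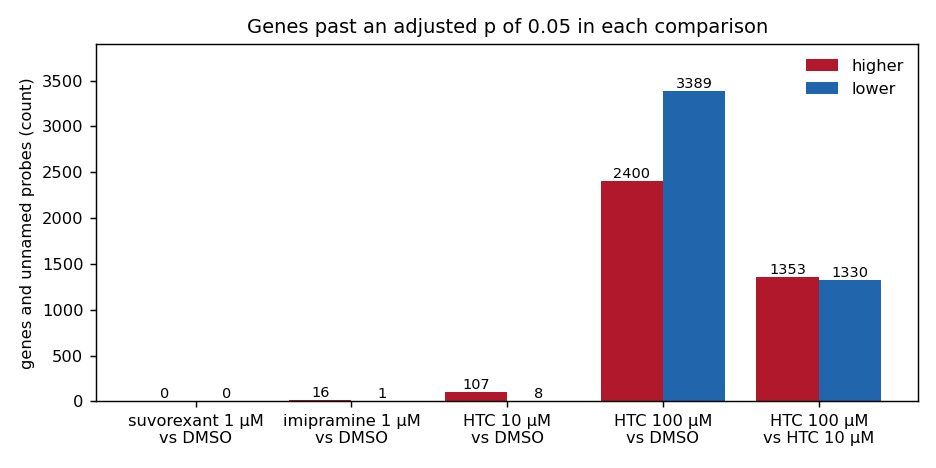
The bars give, for each comparison on the x axis, the number of genes and unnamed probes (y axis, count) that were higher or lower at an adjusted p under 0.05. The numbers were 0 for suvorexant, 16 higher and 1 lower for imipramine, 107 and 8 for HTC at 10 µM, 2400 and 3389 for HTC at 100 µM, and 1353 and 1330 between the doses of HTC.

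The comparison of suvorexant with DMSO asked which brain transcripts differ after 3 h of orexin receptor block. The transcript of hcrt, which encodes the orexin precursor, stood at a log2 difference of -0.0045 ± 0.19 (SE, n = 3 per group). The genes with the smallest p among those higher included slc34a2a, a sodium-phosphate cotransporter, at 2.08 ± 0.41, and the connexin gene gja13.1 at 0.73 ± 0.17. Among those lower were pofut2, a protein O-fucosyltransferase, at -0.49 ± 0.09 and glg1b, a Golgi glycoprotein, at -0.84 ± 0.24. The immediate early gene nr4a1 stood at 0.98 ± 0.26 and nr1d2a, a repressor in the circadian clock, at 1.26 ± 0.37. None of these passed (adjusted p = 1.00 for each). In limma, 0 of 24315 transcripts passed, 564 had an unadjusted p under 0.05, and 1215.75 would by chance.

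Of the 30 gene lists, 15 passed the list test for suvorexant (13 higher and 2 lower), although no member of any list passed over all genes, and 1 member passed adjusted over the list alone, in the cartilage and connective tissue list. The 33 glucocorticoid-responsive genes had a median of 0.18 (adjusted p = 6.8e-06, and adjusted p = 0.50 with an estimated correlation). Their medians were 0.16 in session 1 and 0.23 in session 2, with an adjusted p of 2.7e-06 when the session was a block. The 93 genes of mitochondrial respiration had a median of 0.11 (adjusted p = 2.2e-13, and adjusted p = 0.70 with an estimated correlation). The sessions gave 0.15 and 0.08, with an adjusted p of 5.5e-13 with the session as a block. The 29 genes of GABA and glutamate signalling had a median of -0.17 (adjusted p = 0.00054, and adjusted p = 0.80 with an estimated correlation), with -0.15 in each session and an adjusted p of 0.0013 with the block. For the 29 sleep-wake neuropeptides the median was -0.0045 and the mean -0.01, the test leaned to higher values, and the list did not pass (adjusted p = 0.88). Without DMSO replicate 1 only 5 lists passed. The call on GABA and glutamate signalling ended without DMSO replicate 1 or 2 or suvorexant replicate 2 (adjusted p = 0.082, 0.54 and 0.18, within a range over all settings of 1.3e-09 to 0.54).

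Markers of other cells and tissues moved beside these lists with suvorexant. Liver, gut and pancreas markers had a median of 0.21 (adjusted p = 2.1e-06, and adjusted p = 0.80 with an estimated correlation). Cartilage and connective tissue markers had a median of 0.19 (adjusted p = 1.2e-07, and 0.70 with an estimated correlation). Markers of skeletal muscle, which is rich in mitochondria, had a median of 0.09 (adjusted p = 3.4e-06, and 0.80 with an estimated correlation), with -0.10, 0.44 and 0.01 on suvorexant replicates 1, 2 and 3. The medians of microglia and blood cell markers were 0.10 and 0.14 (adjusted p = 0.00020 and 0.0020, and 0.70 for each with an estimated correlation). Without DMSO replicate 1 the calls on liver and gut, cartilage, muscle, microglia and blood ended (adjusted p = 0.052, 0.055, 0.46, 0.096 and 0.26). Those on muscle and blood also ended without suvorexant replicate 2 (adjusted p = 0.72 and 0.21), where the muscle list turned lower. Over all settings these lists ranged over 6.0e-09 to 0.052, 1.9e-10 to 0.055, 1.1e-19 to 0.72, 1.6e-06 to 0.29 and 2.2e-05 to 0.26. The other lists that passed were monoamine signalling, with a median of -0.12, immediate early genes at 0.09, Nrf2 at 0.09, xenobiotic metabolism at 0.06, p53 at 0.07, cell proliferation at 0.08 and the proteasome at 0.08. Their adjusted p lay between 7.2e-05 and 0.036, and between 0.50 and 0.80 with an estimated correlation. Each of these calls ended without 1 or more of DMSO replicates 1 and 2 and suvorexant replicates 1, 2 and 3 (adjusted p up to 0.96).

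In imipramine-treated brains 16 transcripts rose and 1 fell relative to DMSO. The largest rise among named genes was that of ponzr3, by 3.84 ± 0.61 on the log2 scale (adjusted p = 0.0491). The clock repressor nr1d2a rose by 2.61 ± 0.37 (adjusted p = 0.0453) and the neutral amino acid transporter gene slc6a19a.1 by 2.57 ± 0.40 (adjusted p = 0.0466). The titin-binding gene tcap rose by 1.76 ± 0.22 (adjusted p = 0.0239) and pdk2b, a pyruvate dehydrogenase kinase, by 0.93 ± 0.15 (adjusted p = 0.0466). For cyp8b1.3, a sterol hydroxylase not well above background in DMSO, the level was at least 3.09-fold higher with intensities floored at 1 (adjusted p = 0.0239). The single fall was that of an unnamed probe, A_15_P567777, which is named here because of its value. It was well above background on all 3 DMSO arrays and on no imipramine array, and was at least 3.50-fold lower with that floor (adjusted p = 0.0466). In each of these the 3 imipramine arrays lay beyond all 3 DMSO arrays, as 10% of unselected transcripts do by chance. Selection at the threshold favours such separation, so it adds no support. The serotonin transporter gene slc6a4a, whose product imipramine binds, stood at -0.11 ± 0.13 (adjusted p = 0.80) and hcrt at -0.26 ± 0.19 (adjusted p = 0.65). The glucocorticoid-induced chaperone gene fkbp5, chosen after its values were seen, stood at 4.05 ± 0.68 (adjusted p = 0.0529). The glucuronosyltransferase gene ugt5a1 did not pass (adjusted p = 0.0516), and its fold is not given, since it was well above background on 1 imipramine array and on no DMSO array.

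The imipramine count of 17 was 75 (68 higher and 7 lower) in the fit with the replicate number as a block, which pairs the samples in this comparison. In that fit fkbp5 and ugt5a1 passed (adjusted p = 0.0377 and 0.0207). Their adjusted p lay within ranges over all settings of 0.0065 to 0.53 for fkbp5 and 0.011 to 1.00 for ugt5a1. With the scan session as a block 139 transcripts passed, 118 of them higher. By contrast 0 passed in limma on session 2 alone, with 2 arrays per group. After normexp background correction 45 were higher and 20 lower (69.2% higher, against 94.1%). The count was 27, 3 and 0 without DMSO replicates 1, 2 and 3. It was 7, 66 and 359 without suvorexant replicates 1, 2 and 3, and 0, 5 and 0 without imipramine replicates 1, 2 and 3. It was 30, 3 and 5 without HTC 10 µM replicates 1, 2 and 3, and 6, 3 and 10 without HTC 100 µM replicates 1, 2 and 3. Leaving out any array other than suvorexant replicate 2 or 3 or HTC 10 µM replicate 1 ended the call of at least 1 of ponzr3, nr1d2a, slc6a19a.1, tcap, pdk2b, cyp8b1.3 and A_15_P567777 (adjusted p up to 0.21). With intensities floored at 16 the count was 12 (8 higher and 4 lower), and of these 7 calls only that on tcap held (adjusted p = 0.0459). Those on ponzr3, nr1d2a, slc6a19a.1 and pdk2b ended with the same log2 differences (adjusted p = 0.064, 0.056, 0.060 and 0.054). Those on cyp8b1.3 and A_15_P567777 ended at log2 differences of 0.23 and -0.30 (adjusted p = 0.43 and 0.40, within ranges of 0.00044 to 0.43 and 0.011 to 0.49). Both are smaller than the bounds of 3.09-fold and 3.50-fold, so those bounds depend on the floor. After normexp correction the 2 stood at 0.25 and -0.41 (adjusted p = 0.15 and 0.0475), also smaller than the bounds. Without the filter on dim probes only the calls on tcap and cyp8b1.3 held, with only the 2 groups those on nr1d2a, slc6a19a.1 and pdk2b ended, with the mean of a gene's probes that on pdk2b did, and with the slide fixed all 7 ended.

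Among the lists, glucocorticoid-responsive genes were higher with imipramine. Of 33 members 1 rose, pdk2b, and 11 rose and 1 fell when adjusted over the list alone. Their median was 0.35 (adjusted p = 4.8e-06, and adjusted p = 0.72 with an estimated correlation). In sessions 1 and 2 this was 0.35 and 0.24, and with the session as a block the adjusted p was 3.5e-06. The 47 immediate early genes had a median of 0.19 with no member past the threshold over all genes and 1 adjusted over the list alone (adjusted p = 0.0026, and adjusted p = 1.00 with an estimated correlation). The call on immediate early genes ended without imipramine replicate 1 (adjusted p = 0.14, the highest over all settings, with 2.1e-11 the lowest). Lens markers, 20 genes of a tissue outside the brain of which 17 were above background on every DMSO array and none is in another list, had a median of 0.67 (adjusted p = 0.0031, and adjusted p = 1.00 with an estimated correlation). The median of the lens markers was 1.55 on imipramine replicate 1, 0.26 on replicate 2 and -0.01 on replicate 3. The lens list did not pass without imipramine replicate 1 (adjusted p = 0.51) or without DMSO replicate 3 (adjusted p = 0.056), within a range over all settings of 6.5e-05 to 0.51, and turned lower with the slide fixed (adjusted p = 0.45). With the session as a block the adjusted p was 0.00084 for immediate early genes and 0.0015 for lens markers, whose session medians were 1.56 and 0.19. The 42 genes of monoamine signalling had a median of -0.02, with no member past the threshold (adjusted p = 0.96). Ribosomal proteins and the circadian clock list also passed, at medians of -0.11 and 0.07 (adjusted p = 0.0026 and 0.037, and 1.00 for each with an estimated correlation). The ribosomal call ended without DMSO replicate 1 or 3 or imipramine replicate 2 (adjusted p = 0.29, 0.056 and 0.90, within a range of 8.0e-10 to 0.90). The clock call ended without DMSO replicate 3, suvorexant replicate 3, imipramine replicate 1 or 2 or HTC 100 µM replicate 2 (adjusted p up to 0.23, within a range of 1.8e-06 to 0.31). The arrays that stood apart in lens, eye or gut markers were imipramine replicate 1, HTC 100 µM replicate 2 and HTC 10 µM replicate 3. Without them 0 transcripts passed in limma for imipramine, and 2913 had an unadjusted p under 0.05 with all arrays. Of the 30 lists 5 passed, against 8 without DMSO replicate 1, 9 without DMSO replicate 2 and 2 without imipramine replicate 1.

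HTC at 10 µM raised 107 transcripts and lowered 8 relative to DMSO. Among glucocorticoid-responsive genes, fkbp5 rose by 4.54 ± 0.68 (adjusted p = 0.0111) and hsd11b2, which inactivates cortisol, by 1.75 ± 0.22 (adjusted p = 0.0066). The transcription factor gene klf9 rose by 1.92 ± 0.30 (adjusted p = 0.0125) and tsc22d3, which encodes the leucine zipper protein GILZ, by 1.02 ± 0.14 (adjusted p = 0.0077). Genes of metabolism that rose included pfkfb4b, a regulator of glycolysis, by 2.51 ± 0.34 (adjusted p = 0.0074), and the antizyme gene oaz2b by 2.53 ± 0.34 (adjusted p = 0.0074). The amino acid transporter subunit slc3a2b rose by 1.23 ± 0.16 (adjusted p = 0.0074) and the glutamine synthetase gene glulb by 0.81 ± 0.10 (adjusted p = 0.0056). The glucuronosyltransferase genes ugt5a2 and ugt5a4 rose by 2.44 ± 0.30 and 2.31 ± 0.30 (adjusted p = 0.0060 and 0.0071), and ugt5a1, not well above background on any DMSO array, was at least 2.03-fold higher (adjusted p = 0.0018). The clock gene nr1d2a rose by 2.44 ± 0.37 (adjusted p = 0.0116) and the sulfotransferase gene sult2st1 by 1.27 ± 0.18 (adjusted p = 0.0083). The chemokine gene cxcl18b fell by 0.85 ± 0.13 (adjusted p = 0.0114). Every one of the 115 calls had its 3 HTC arrays beyond all 3 DMSO arrays (10% of unselected transcripts by chance). Selection at the threshold favours such separation, so it adds no support.

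The count at 10 µM was 197 (175 higher and 22 lower) in the fit with the replicate number as a block, which pairs the samples here too, and 205 with the session as a block, but 4 in session 2 alone. It was 29 without DMSO replicate 2, 37 without DMSO replicate 3, and 72, 48 and 39 without HTC 10 µM replicates 1, 2 and 3. The calls on fkbp5, klf9 and nr1d2a ended without DMSO replicate 2 or 3 or HTC 10 µM replicate 2 or 3 (adjusted p up to 0.08). That on sult2st1 ended without DMSO replicate 2 (adjusted p = 0.0569), and that on cxcl18b without DMSO replicate 3 or HTC 10 µM replicate 2 or 3 (adjusted p up to 0.0636). In session 2 alone every call named here but that on ugt5a1 ended (adjusted p up to 0.119). With only the 2 groups 11 transcripts passed, among the genes named here only hsd11b2, ugt5a1 and sult2st1, and with the slide fixed none did. The rises of ugt5a1, ugt5a2 and ugt5a4 did not pass after normexp background correction, where the log2 differences were 0.31, 0.80 and 0.73 (adjusted p = 0.26, 0.069 and 0.052). With intensities floored at 16 ugt5a1 stood at 0.079 (adjusted p = 0.88), below the bound of 2.03-fold, so that bound depends on the floor. Over all settings they ranged over 0.00025 to 0.88, 0.0026 to 0.16 and 0.0032 to 0.16. Without the 3 arrays that stood apart in lens, eye or gut markers 2 transcripts passed. Of the 22 genes past the threshold that the rule gives for this dose, leaving out 1 array ended the calls of 13.

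Of the 33 glucocorticoid-responsive genes 4 rose at 10 µM and none fell, and 11 rose and 1 fell adjusted over the list alone. Their median was 0.20 (adjusted p = 9.7e-10, and adjusted p = 0.22 with an estimated correlation). Session medians were 0.46 and 0.13, with an adjusted p of 1.2e-09 when the session was a block. Of 42 genes of the circadian clock list 1 rose, nr1d2a, and 8 rose adjusted over the list alone. The list had a median of 0.16 (adjusted p = 8.9e-06, and adjusted p = 0.63 with an estimated correlation). The sessions gave -0.10 and 0.36, with an adjusted p of 2.4e-05 with the session as a block. Of 41 genes of NF-kB and inflammation cxcl18b fell, and 4 fell adjusted over the list alone. Their median was -0.19 (adjusted p = 0.018, and adjusted p = 0.66 with an estimated correlation). In sessions 1 and 2 this was -0.09 and -0.22, and with the session as a block the adjusted p was 0.0082, and the NF-kB call ended without DMSO replicate 3 or HTC 10 µM replicate 2 (adjusted p = 0.40 and 0.35, within a range of 0.00065 to 0.46). In the xenobiotic metabolism list 2 of 48 members rose, ugt5a1 and sult2st1, and 4 adjusted over the list alone, with a median of -0.03, a mean of 0.06 and an adjusted p of 0.20. No member of the unfolded protein and ATF4 list passed over all genes, whereas 5 rose and 2 fell adjusted over the list alone. The list had a median of 0.03 and passed (adjusted p = 0.0041, and adjusted p = 0.66 with an estimated correlation). Among its members ddit4 stood at 2.04 ± 0.42 (adjusted p = 0.0588) and chac1, a glutathione-degrading enzyme, at 1.00 ± 0.22 (adjusted p = 0.0756), and both passed with the replicate number as a block (adjusted p = 0.0050 and 0.0091, within ranges of 0.0036 to 0.36 and 0.0053 to 0.30). The 79 ribosomal proteins had a median of -0.07 and did not pass (adjusted p = 0.067), but did with the replicate number or the session as a block (adjusted p = 0.0087 and 0.011, within a range of 4.6e-10 to 0.94, and adjusted p = 0.98 with an estimated correlation). Liver, gut and pancreas markers had medians of 0.52, -0.14 and -0.87 on HTC 10 µM replicates 1, 2 and 3.

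Of the 30 lists 11 passed at 10 µM, 10 of them higher. The 29 sleep-wake neuropeptides had a median of 0.11 (adjusted p = 0.00028, and adjusted p = 0.66 with an estimated correlation), with no member past the threshold over all genes or over the list alone. Their session medians were -0.01 and 0.20. Immediate early genes had a median of 0.14 (adjusted p = 0.00028, and 0.66 with an estimated correlation) and a range over all settings of 9.0e-06 to 0.043. The proteasome stood at 0.11 (adjusted p = 0.00028, and 0.98 with an estimated correlation) and sterol and fatty acid synthesis at 0.13 (adjusted p = 0.0016, and 0.63 with an estimated correlation). Mitochondrial respiration had a median of 0.04 (adjusted p = 0.0062, and 0.98 with an estimated correlation) and Nrf2 of 0.03 (adjusted p = 0.011, and 0.90 with an estimated correlation). The p53 list had a median of 0.01 (adjusted p = 0.035, and 0.63 with an estimated correlation). The sleep-wake call ended without DMSO replicate 3 (adjusted p = 0.053) and turned lower with the slide fixed (adjusted p = 0.74), the proteasome call without DMSO replicate 1 or HTC 10 µM replicate 3 (adjusted p = 0.15 and 0.34), and the sterol call without HTC 10 µM replicate 1 (adjusted p = 0.085). The mitochondrial call ended without DMSO replicate 1 or 2 or HTC 10 µM replicate 1 or 3 (adjusted p up to 0.52). The calls on the unfolded protein, Nrf2 and p53 lists each ended without DMSO replicate 2 (adjusted p = 0.14, 0.097 and 0.18) and without HTC 10 µM replicate 1 (adjusted p = 0.23, 0.28 and 0.20). Over all settings the sleep-wake, proteasome, sterol and mitochondrial lists ranged over 2.0e-05 to 0.74, 3.6e-07 to 0.37, 2.9e-05 to 0.085 and 3.5e-09 to 0.62. The unfolded protein, Nrf2 and p53 lists ranged over 8.0e-06 to 0.23, 3.9e-06 to 0.28 and 0.0075 to 0.21.

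**Figure D2:**
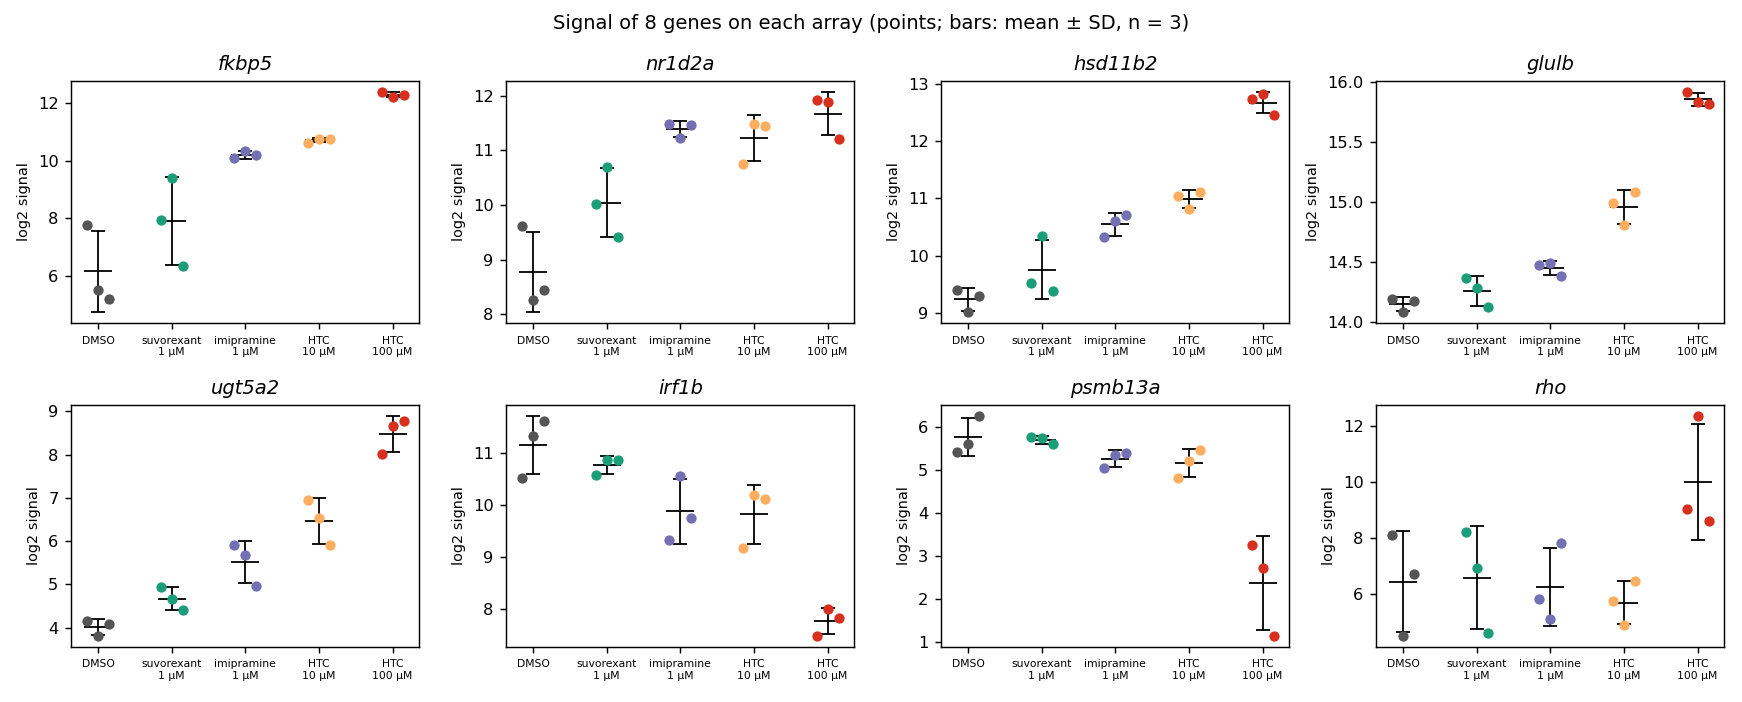
Each panel plots the log2 signal (y axis) of 1 gene on the 15 arrays, with the groups on the x axis, points for single arrays and bars for the mean ± SD (n = 3). The panels show fkbp5, nr1d2a, hsd11b2, glulb, ugt5a2, irf1b, psmb13a and rho, and the fkbp5 signal lay between 12.21 and 12.38 on the arrays of HTC at 100 µM and between 5.18 and 7.78 on those of DMSO.

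HTC at 100 µM changed 5789 of 24315 transcripts relative to DMSO, of which 2400 rose and 3389 fell. The counts of list members given for this dose are to be read beside these shares. The largest rise among named genes was that of fkbp5, by 6.13 ± 0.68 on the log2 scale (adjusted p = 6.1e-05). The integrin gene itga6b rose by 4.52 ± 0.23 (adjusted p = 9.0e-07) and the forkhead gene foxg1b by 4.25 ± 0.37 (adjusted p = 1.2e-05). The kinase gene stk35 rose by 4.04 ± 0.48 (adjusted p = 1.0e-04) and the keratin gene krt98 by 3.62 ± 0.23 (adjusted p = 2.0e-06). The largest falls included plekhs1.1, by -3.42 ± 0.39 (adjusted p = 7.7e-05), the interferon regulatory factor gene irf1b, by -3.39 ± 0.35 (adjusted p = 3.8e-05), and the epithelial transcription factor gene ehf, by -2.96 ± 0.32 (adjusted p = 4.9e-05). Of the transcripts past the threshold 855 rose and 598 fell at least 2-fold. In 5630 the 3 arrays of one group lay beyond all 3 of the other (10% of unselected transcripts by chance), which selection at the threshold favours. The number past the threshold was 3644 without DMSO replicate 2 and 3851 without HTC 100 µM replicate 3, 6905 with the session as a block, and 4272 in session 2 alone. Of the 170 named genes past the threshold that the rule fixed beforehand gives for this dose, leaving out 1 array ended the calls of 64. The genes printed here were taken from those 170 after that was known, mostly from those that kept their calls. Only replicate 1 of this dose shares a slide with another group, so a fit with the slide fixed rests on 1 array of this dose. With the slide as a fixed block only 99 transcripts passed (81 higher and 18 lower). Of the 60 values past the threshold printed for this dose, the log2 difference fell below 0.5 times its reported size for 16 after normexp correction, 6 with the slide fixed and 1 with a floor of 16. Among these, over all settings, cyp2k6 ranged over 0.77 to 3.40, psmb13a over -3.99 to -0.84, foxg1b over 1.74 to 5.52 and irf1a over -2.95 to -1.03, each smallest after normexp correction. Among the genes named for this dose, hsd11b2, glulb, ugt5a1, ugt5a4, itga6b, krt98, chac1, slc3a2b, tp53inp1 and sult2st1 were past the threshold with the slide as a fixed block.

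Of the 33 glucocorticoid-responsive genes 18 rose and 3 fell at 100 µM, and 21 rose and 7 fell adjusted over the list alone. Besides fkbp5, hsd11b2 rose by 3.44 ± 0.22 (adjusted p = 1.9e-06), pck1, an enzyme of gluconeogenesis, by 3.37 ± 0.36 (adjusted p = 4.8e-05), and ddit4, an inhibitor of mTORC1 signalling, by 3.34 ± 0.42 (adjusted p = 0.00015). The genes of the glucocorticoid receptor, nr3c1, and of the mineralocorticoid receptor, nr3c2, fell by 0.75 ± 0.11 and 1.19 ± 0.17 (adjusted p = 0.00038 and 0.00040). The list had a median of 0.83 (adjusted p = 3.6e-07, and adjusted p = 0.49 with an estimated correlation). Session medians were 0.84 and 0.88, with an adjusted p of 3.1e-07 when the session was a block. In the circadian clock list 16 of 42 genes rose and 5 fell, the same numbers as adjusted over the list alone. The repressor genes nfil3-6, nr1d2a and bhlhe41 rose by 3.07 ± 0.36, 2.89 ± 0.37 and 2.59 ± 0.28 (adjusted p = 9.3e-05, 0.00019 and 5.4e-05). The activator genes bmal1a and bmal2 fell by 0.75 ± 0.13 and 0.67 ± 0.14 (adjusted p = 0.0014 and 0.0048). The light-responsive clock gene per2 rose by 1.18 ± 0.33 (adjusted p = 0.0211), a call that ended without DMSO replicate 2 or 3 or HTC 100 µM replicate 2 or 3 (adjusted p up to 0.0831). The clock list had a median of 0.27 (adjusted p = 0.00035, and adjusted p = 0.78 with an estimated correlation). The sessions gave 0.25 and 0.45, with an adjusted p of 0.00039 with the session as a block. Of 47 immediate early genes 12 rose and 1 fell, also adjusted over the list alone. Among them rgs2, a regulator of G-protein signalling, rose by 3.35 ± 0.34 (adjusted p = 3.0e-05), the MAP kinase phosphatase gene dusp1 by 1.88 ± 0.24 (adjusted p = 0.00018) and btg2 by 1.63 ± 0.33 (adjusted p = 0.0041). Their median was 0.21 (adjusted p = 0.00050, and adjusted p = 0.78 with an estimated correlation). In sessions 1 and 2 this was 0.37 and 0.24, and with the session as a block the adjusted p was 0.00036.

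Genes of NF-kB and inflammation were lower at 100 µM, where 20 of 41 fell and 4 rose (21 and 5 adjusted over the list alone). Besides irf1b, its paralogue irf1a fell by 2.75 ± 0.25 (adjusted p = 1.4e-05) and irg1l, which encodes an itaconate-producing enzyme of activated macrophages, by 3.01 ± 0.54 (adjusted p = 0.0018). The members that rose included inhibitors of inflammatory signalling, nfkbiab by 1.54 ± 0.20 (adjusted p = 0.00020) and socs3a by 1.54 ± 0.30 (adjusted p = 0.0034), and the transcription factor gene cebpd by 1.11 ± 0.20 (adjusted p = 0.0016). The list had a median of -0.64 (adjusted p = 0.0016, and adjusted p = 0.71 with an estimated correlation). Session medians were -0.62 and -0.61, with an adjusted p of 0.0013 when the session was a block. In the proteasome list 5 of 44 members rose and 5 fell, with a median of 0.12, a mean of -0.04 and a test in the direction of higher values (adjusted p = 0.032, and adjusted p = 0.87 with an estimated correlation). The proteasome members that fell most were subunits of the interferon-inducible immunoproteasome, psmb13a by 3.38 ± 0.41 (adjusted p = 0.00012), psmb12 by 1.89 ± 0.32 (adjusted p = 0.0014) and psmb9a by 1.59 ± 0.22 (adjusted p = 0.00029). The proteasome call ended without DMSO replicate 1 or HTC 100 µM replicate 2 or 3 (adjusted p = 0.32, 0.34 and 0.15, within a range of 0.00041 to 0.42), and its adjusted p with the session as a block was 0.019. Of 35 microglia markers 2 rose and 5 fell, also adjusted over the list alone, with mpeg1.2, a perforin-like gene of macrophages, lower by 2.08 ± 0.27 (adjusted p = 0.00020). The microglia list had a median of -0.19 and did not pass against DMSO (adjusted p = 0.078). It was lower than with suvorexant and with imipramine (adjusted p = 0.0011 and 0.022, and 0.78 and 0.85 with an estimated correlation). The inflammasome adaptor gene pycard, a member of the skin and epithelial list, fell by 2.04 ± 0.18 (adjusted p = 1.3e-05), while the desmosomal gene dsc2l rose by 2.17 ± 0.32 (adjusted p = 0.00046). In that list 9 of 54 members rose and 10 fell (10 and 10 adjusted over the list alone) with a median of -0.02 and a test in the direction of higher values (adjusted p = 0.28).

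Stress and detoxification genes moved in both directions at 100 µM, as did transcripts in general (2400 of 24315 higher and 3389 lower). The shares that passed in either direction in the Nrf2 and heat shock lists lay near that of all transcripts. In these lists rises outnumbered falls (10 and 1 of 50, 8 and 4 of 48), whereas falls outnumbered rises over all transcripts. Of 52 genes of the unfolded protein and ATF4 list 10 rose and 6 fell (11 and 8 adjusted over the list alone). In it chac1 was higher by 2.86 ± 0.22 (adjusted p = 4.1e-06) and the pseudokinase gene trib3 by 1.31 ± 0.19 (adjusted p = 0.00043). The list had a median of 0.12 (adjusted p = 0.026, and adjusted p = 0.82 with an estimated correlation), and its call ended without DMSO replicate 2 or HTC 100 µM replicate 3 (adjusted p = 0.10 and 0.077, within a range of 0.0045 to 0.44). Of 50 genes of the Nrf2 oxidative stress response 10 rose and 1 fell, the same numbers as adjusted over the list alone. In it slc3a2b was higher by 2.24 ± 0.16 (adjusted p = 3.5e-06) and the transporter gene abcc4 by 1.38 ± 0.13 (adjusted p = 2.2e-05). The Nrf2 list had a median of 0.11 (adjusted p = 0.0024, and adjusted p = 0.78 with an estimated correlation), which was -0.08 in session 1 and 0.23 in session 2. It did not pass after quantile normalization (adjusted p = 0.075, within a range of 5.0e-06 to 0.33). In the heat shock response list 8 of 48 rose and 4 fell (9 and 4 adjusted over the list alone). The chaperone genes hspa8b and hspa4a rose by 0.95 ± 0.12 and 0.69 ± 0.17 (adjusted p = 0.00018 and 0.0097). The steroid receptor co-chaperone gene fkbp4 fell by 1.07 ± 0.16 (adjusted p = 0.00060) and hsp70l by 1.68 ± 0.46 (adjusted p = 0.0195). The call on hsp70l ended without DMSO replicate 2 or 3 or HTC 100 µM replicate 2 (adjusted p up to 0.0777). The heat shock list had a median of 0.20 (adjusted p = 0.011, and adjusted p = 0.78 with an estimated correlation) and did not pass without HTC 100 µM replicate 3 (adjusted p = 0.076, within a range of 0.0047 to 0.12). Session medians were 0.01 and 0.12 for the unfolded protein list and 0.14 and 0.18 for heat shock. With the session as a block the adjusted p was 0.014, 0.0016 and 0.0063 for the unfolded protein, Nrf2 and heat shock lists. Of 26 p53 response genes 7 rose and 3 fell (8 and 4 adjusted over the list alone), with tp53inp1 higher by 1.68 ± 0.14 (adjusted p = 6.9e-06). The p53 list did not pass (median 0.04, adjusted p = 0.078).

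Among 48 genes of xenobiotic metabolism 9 rose and 3 fell at 100 µM, also adjusted over the list alone. The rises included cyp2k6, a cytochrome P450 gene, by 2.99 ± 0.57 (adjusted p = 0.0028) and sult2st1 by 2.57 ± 0.18 (adjusted p = 2.7e-06). For ugt5a1, not well above background in DMSO, the level was at least 8.24-fold higher (adjusted p = 2.0e-06), and ugt5a2 and ugt5a4 rose by 4.46 ± 0.30 and 3.98 ± 0.30 (adjusted p = 2.5e-06 and 4.3e-06). After normexp correction and with a floor of 16 the log2 difference of ugt5a1 was 0.92 and 1.64, below that bound, and past the threshold (adjusted p = 1.5e-05 and 3.5e-08, within a range of 3.5e-08 to 0.036). The xenobiotic list had a median of -0.06 and a mean of 0.27 and did not pass (adjusted p = 0.14). Of 43 genes of sterol and fatty acid synthesis 9 rose and none fell, also adjusted over the list alone. The phosphatidate phosphatase gene lpin1a was higher by 1.34 ± 0.27 (adjusted p = 0.0041). The sterol list had a median of 0.22 (adjusted p = 0.00070, and adjusted p = 0.71 with an estimated correlation). The sessions gave 0.02 and 0.32, with an adjusted p of 0.00069 with the session as a block. Of 93 genes of mitochondrial respiration 6 rose and 1 fell (2 and 1 adjusted over the list alone). The complex I assembly gene ndufaf2 was higher by 1.56 ± 0.11 (adjusted p = 3.0e-06) on the brighter of its 2 probes and by 0.24 on the other. The mitochondrial list had a median of 0.13 (adjusted p = 9.7e-05, and adjusted p = 0.87 with an estimated correlation). In sessions 1 and 2 this was 0.06 and 0.13, and with the session as a block the adjusted p was 9.7e-05, and it did not pass after quantile normalization (adjusted p = 0.16, within a range of 1.0e-08 to 0.44). Skeletal muscle markers had medians of -0.09, 0.20 and 0.26 on HTC 100 µM replicates 1, 2 and 3, and 0.11 overall (adjusted p = 0.0024, and adjusted p = 0.87 with an estimated correlation). The muscle call ended without DMSO replicate 1 or HTC 100 µM replicate 3 (adjusted p = 0.17 and 0.076, within a range of 8.3e-06 to 0.17). Liver, gut and pancreas markers had medians of -0.27, 0.34 and 0.46 on HTC 100 µM replicates 1, 2 and 3. They too moved beside these lists, with a median of 0.16 (adjusted p = 0.041, and adjusted p = 0.87 with an estimated correlation). That call ended without DMSO replicate 1 or HTC 100 µM replicate 2 or 3 (adjusted p = 0.32, 0.25 and 0.36, within a range of 0.00015 to 0.36), and with the slide fixed the list was lower (adjusted p = 0.00030). All 54 liver, gut and pancreas markers were above background on every DMSO array, and 1 is in another list.

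Neuronal and glial transcripts changed in both directions at 100 µM, as did transcripts in general (2400 of 24315 higher and 3389 lower). Beside that share fewer synaptic markers and sleep-wake neuropeptides passed, and more astroglia markers did. Monoamine and proliferation genes were near it when rises and falls were counted jointly, but 1 proliferation gene rose and 11 fell. Of 42 genes of monoamine signalling 5 rose and 6 fell at 100 µM (5 and 7 adjusted over the list alone). The tryptophan hydroxylase gene tph1b, which encodes an enzyme of serotonin synthesis, rose by 1.16 ± 0.12 (adjusted p = 4.6e-05) and the alpha-2A adrenergic receptor gene adra2a by 1.53 ± 0.15 (adjusted p = 2.2e-05). The serotonin transporter gene slc6a4a fell by 0.45 ± 0.13 (adjusted p = 0.0241). Its call ended after normexp background correction (adjusted p = 0.27) and without DMSO replicate 1 or 3 or HTC 100 µM replicate 2 or 3 (adjusted p up to 0.0829). With the slide fixed the sign of slc6a4a turned. The monoamine list had a median of -0.09 and a mean of -0.05, with a test in the direction of higher values (adjusted p = 0.64). Of 29 sleep-wake neuropeptides 3 rose and 1 fell (1 and 0 adjusted over the list alone), and the orexin gene hcrt stood at -0.21 ± 0.19 (adjusted p = 0.44). That list had a median of 0.04 (adjusted p = 0.20). Of 32 markers of astroglia and radial glia 4 rose and 9 fell (4 and 11 adjusted over the list alone). There glulb was higher by 1.71 ± 0.10 (adjusted p = 9.0e-07) and the GABA transporter gene slc6a11a lower by 1.26 ± 0.17 (adjusted p = 0.00022). The glial list had a median of -0.16 and did not pass (adjusted p = 0.64). Per array the astroglia medians of HTC 100 µM replicates 1, 2 and 3 were -0.22, -0.12 and -0.12. Those of oligodendrocytes were -0.24, -0.15 and -0.16, and those of microglia -0.34, -0.15 and -0.27. Each lay below all 3 DMSO arrays, and separation in either direction occurs in 10% by chance. The median log2 difference over all transcripts was itself -0.10 at this dose. Of 48 synaptic and neuronal markers 4 rose and 2 fell, also adjusted over the list alone. The sodium pump gene atp1a3b rose by 0.91 ± 0.16 (adjusted p = 0.0015), and gap43 and elavl3, markers of growing axons and of young neurons, fell by 0.65 ± 0.13 and 0.68 ± 0.14 (adjusted p = 0.0044 and 0.0050). The synaptic list had a median of -0.15 (adjusted p = 0.55). Of 53 genes of cell proliferation 1 rose and 11 fell, also adjusted over the list alone. The replication genes mcm6 and lig1 were lower by 0.75 ± 0.17 and 0.62 ± 0.09 (adjusted p = 0.0079 and 0.00044), but the list did not pass (median -0.22, adjusted p = 0.075).

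Photoreceptor and retina markers, of which 41 of 44 were above background on every DMSO array and 1 is in another list, were higher at 100 µM. Over all genes 8 rose and 1 fell, and none passed adjusted over the list alone, where 0 of 44 passed in limma. The rod opsin gene rho rose by 3.55 ± 1.19 (adjusted p = 0.0470), with 0.93 in session 1 and 4.86 in session 2. The call on rho ended without DMSO replicate 2 or 3, suvorexant replicate 2, imipramine replicate 1 or 2, any HTC 10 µM array or HTC 100 µM replicate 1 or 2 (adjusted p up to 0.19). It also ended with the replicate block, array weights, only the 2 groups, no filter on dim probes and a floor of 16 (adjusted p = 0.060, 0.064, 0.099, 0.065 and 0.070). The list had a median of 0.60 (adjusted p = 0.00017, and adjusted p = 0.78 with an estimated correlation). Session medians were -0.17 and 0.88, with an adjusted p of 0.00036 when the session was a block. With the slide fixed the call ended and the list turned lower (adjusted p = 0.98, within a range of 2.1e-08 to 0.98). Per array the median was 0.22, 0.83 and 0.45 for HTC 100 µM replicates 1, 2 and 3 and 0.35, -0.09 and -0.32 for DMSO replicates 1, 2 and 3. Lens markers did not move with them, at a median of -0.22 and a mean of -0.07, with a test in the direction of higher values (adjusted p = 0.61, with 1 of 20 past the threshold). Without HTC 100 µM replicate 2, imipramine replicate 1 and HTC 10 µM replicate 3 the number of transcripts past the threshold at 100 µM was 3804 (1672 higher and 2132 lower). Of the 30 lists 13 passed at this dose, against 8 without HTC 100 µM replicate 3.

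**Figure D3:**
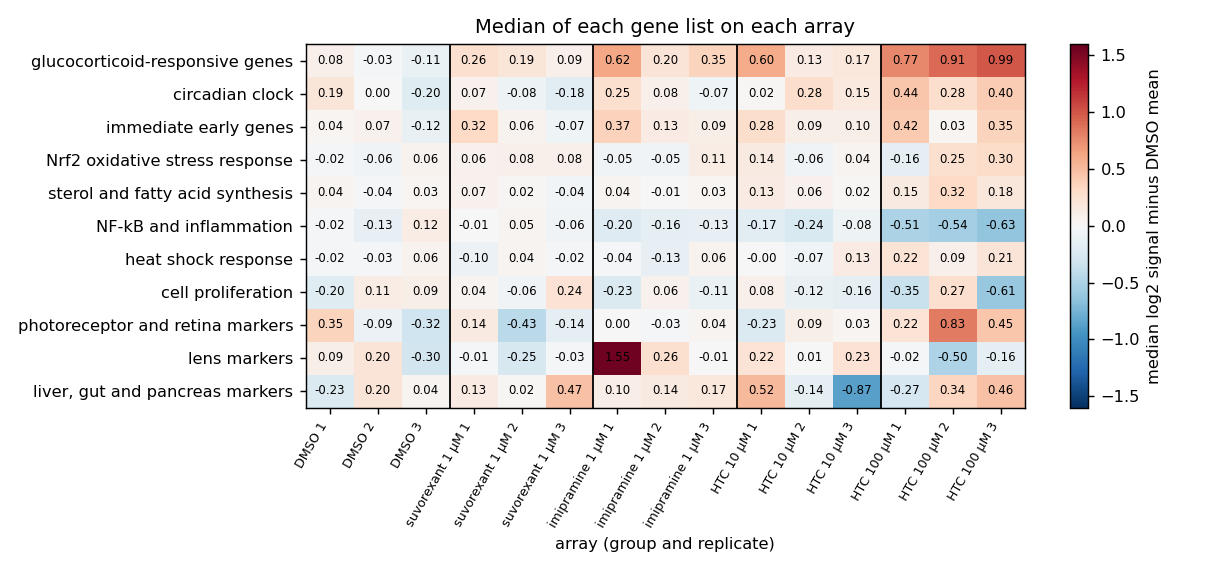
Each cell gives, for 1 gene list (y axis) on 1 array (x axis, group and replicate), the median log2 signal of its genes after subtracting each gene's mean over the DMSO arrays, with red for higher and blue for lower. Glucocorticoid-responsive genes lay at 0.77, 0.91 and 0.99 on the arrays of HTC at 100 µM and at 0.08, -0.03 and -0.11 on those of DMSO.

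The doses of HTC were compared directly. At 100 µM 1353 transcripts were higher and 1330 lower than at 10 µM, 2683 in all. The integrin gene itga6b was higher by 3.14 ± 0.23 (adjusted p = 3.9e-05), krt98 by 2.65 ± 0.23 (adjusted p = 8.6e-05) and the matrix protein gene mgp by 2.62 ± 0.22 (adjusted p = 7.6e-05). The gene rgs2 was higher by 2.44 ± 0.34 (adjusted p = 0.0012) and ugt5a1 by 2.02 ± 0.33 (adjusted p = 0.0033). The macrophage gene mfap4.4 stood at -3.02 ± 0.48 (adjusted p = 0.0027) and psmb13a at -2.78 ± 0.41 (adjusted p = 0.0017). The sulfotransferase gene sult5a1 stood at -2.62 ± 0.31 (adjusted p = 0.00049), mpeg1.2 at -1.76 ± 0.27 (adjusted p = 0.0023) and pycard at -1.55 ± 0.18 (adjusted p = 0.00041). The number was 1103 and 1175 without HTC 10 µM replicates 2 and 3, and 1620 and 1255 without HTC 100 µM replicates 2 and 3. It was 3933 with the session as a block, 2013 in session 2 alone and 1784 with the slide as a random block. In the main fit 6942 had an unadjusted p under 0.05 in limma. With the slide as a fixed block, where only replicate 1 of each dose informs the difference, none of the printed gene calls held. Of the 20 values past the threshold printed for this comparison, the log2 difference fell below 0.5 times its size for 5 after normexp correction, and each of the 5 still passed. They were psmb13a at -0.57, irf1a at -0.70, ugt5a1 at 0.60, mgp at 1.19 and bhlhe41 at 0.83. It did so for psmb13a with a floor of 16 (-1.15), and for psmb13a and pdk2b with the slide fixed (-1.20 and 0.61). Of the 117 genes past the threshold that the rule gives for this comparison, leaving out 1 array ended the calls of 62, and the genes printed here are mostly others. Without the 3 arrays that stood apart in lens, eye or gut markers the number of transcripts was 592 (299 higher and 293 lower), and the call on ugt5a1 ended (adjusted p = 0.06, within a range of 7.9e-08 to 0.54).

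Between the doses 10 of 33 glucocorticoid-responsive genes were higher and 2 lower (14 and 4 adjusted over the list alone). Of these hsd11b2 was higher by 1.68 ± 0.22 (adjusted p = 0.00077) and pdk2b by 1.37 ± 0.15 (adjusted p = 0.00027). Their median was 0.47 (adjusted p = 0.00012, and adjusted p = 0.87 with an estimated correlation). The sessions gave 0.17 and 0.65, with an adjusted p of 7.6e-05 with the session as a block. Genes of NF-kB and inflammation were lower at the higher dose, where 16 of 41 fell and 2 rose (16 and 3 adjusted over the list alone). Of these irf1a was lower by a log2 difference of -2.15 ± 0.25 (adjusted p = 0.00038) and the chemokine gene ccl20a.3 by -1.95 ± 0.22 (adjusted p = 0.00034). Their median was -0.33 (adjusted p = 0.0033, and adjusted p = 0.87 with an estimated correlation). In sessions 1 and 2 this was -0.34 and -0.30, and with the session as a block the adjusted p was 0.0031. In the circadian clock list bhlhe41 was higher by 1.93 ± 0.28 (adjusted p = 0.0017). Further genes that were higher at 100 µM were chac1, by 1.86 ± 0.22 (adjusted p = 0.00038), tph1b, by 1.00 ± 0.12 (adjusted p = 0.00058), adra2a, by 1.01 ± 0.15 (adjusted p = 0.0016), and glulb, by 0.90 ± 0.10 (adjusted p = 0.00029). Photoreceptor and retina markers had a median of 0.54 (adjusted p = 2.1e-05, and adjusted p = 0.87 with an estimated correlation), with 4 of 44 higher, 5 higher and 1 lower adjusted over the list alone, 0.47 and 0.52 in the sessions and an adjusted p of 7.6e-05 with the block. The call on rho, at 4.29 ± 1.19 (adjusted p = 0.0375), ended without any of the HTC 10 µM arrays and without HTC 100 µM replicate 2 or 3 (adjusted p up to 0.13). It also ended with only the 2 groups, no filter on dim probes and a floor of 16 (adjusted p = 0.056, 0.055 and 0.055). Liver, gut and pancreas markers had a median of 0.33 (adjusted p = 0.0015, and adjusted p = 0.87 with an estimated correlation), which was -0.75 in session 1 and 0.89 in session 2. Their call ended without HTC 10 µM replicate 3 or HTC 100 µM replicate 3 (adjusted p = 0.85 and 0.070, within a range of 5.9e-18 to 0.85 over the settings in which they were higher). With the slide fixed the same list was lower, at an adjusted p of 4.6e-20, and it turned lower without the 3 arrays that stood apart (adjusted p = 0.56). The other lists that passed were mitochondrial respiration, at a median of 0.08, skeletal muscle markers at 0.15, Nrf2 at 0.10, heat shock at 0.16, immediate early genes at 0.11, sterol synthesis at 0.14, ribosomal proteins at 0.06 and the circadian clock at 0.09. Their adjusted p lay between 0.00088 and 0.038, and was 0.87 for each with an estimated correlation. Each of these calls ended without 1 or more of the HTC 10 µM and 100 µM arrays (adjusted p up to 0.86), and that on ribosomal proteins also without suvorexant replicate 3 (adjusted p = 0.054). With the slide fixed the mitochondrial, ribosomal, Nrf2 and sterol lists turned lower (adjusted p = 0.010, 0.044, 0.37 and 0.53). Of the 30 lists 12 passed, against 7 without HTC 10 µM replicate 3 and 5 without HTC 100 µM replicate 3.

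**Figure D4:**
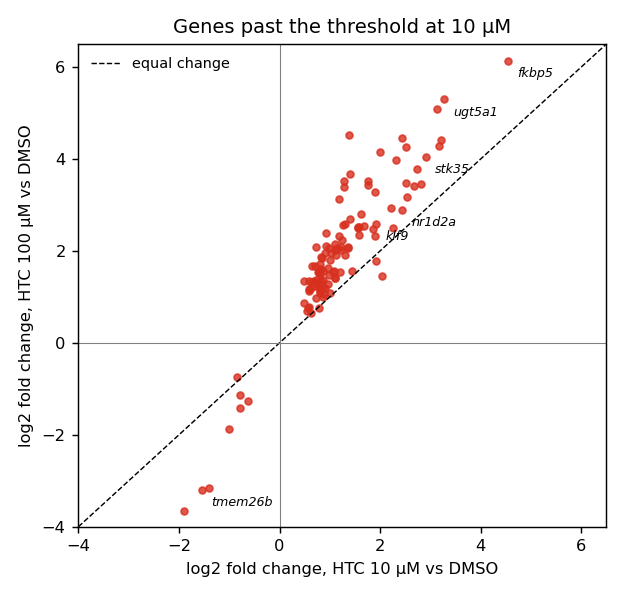
Each point is 1 of the 115 transcripts past the threshold at 10 µM, with its log2 fold change against DMSO at 10 µM on the x axis and at 100 µM on the y axis, and the dashed line marks equal changes. All 107 transcripts higher at 10 µM and all 8 lower at 10 µM were past the threshold in the same direction at 100 µM.

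All comparisons with DMSO share the same 3 control arrays. The 107 rises and 8 falls at 10 µM were all called in the same direction at 100 µM, where independent sets would share 10.6 and 1.12. In simulated unchanged groups with a shared simulated control, the same numbers of transcripts were taken by rank, whether or not they passed. These shared a median of 61 and 6 and at most 107 and 8. Imipramine shared 9 of its 16 rises with HTC at 10 µM (0.0704 if independent, 3 in the simulation, at most 14). It shared 14 with HTC at 100 µM (1.58 if independent, 11 in the simulation, at most 16), and its single fall with both. Across transcripts, which are not independent replicates, the log2 fold changes of HTC at 10 µM and 100 µM correlated at r = 0.622 (rho = 0.539). Of 1000 simulated pairs of unchanged groups 384 gave an r as large (median 0.533, with 95% between -0.223 and 0.897). For imipramine and HTC at 100 µM r was 0.674 (rho = 0.622), and 292 of 1000 were as large (median 0.536, -0.249 to 0.892). For imipramine and HTC at 10 µM r was 0.371 (rho = 0.308, 709 as large), and for suvorexant and imipramine 0.547 (rho = 0.498, 485 as large). Suvorexant correlated with HTC at 10 µM and 100 µM at 0.362 and 0.448 (rho = 0.315 and 0.439, 695 and 641 as large). Each r thus lay within the spread that unchanged groups gave. No group of the simulation held changed transcripts, whereas 5789 differed from DMSO at HTC 100 µM. The simulated r and overlaps therefore do not show what a shared control alone would give beside such a response. For the pairs with HTC at 100 µM they cannot decide whether the similarity exceeds it. The covariance was 0.136 for imipramine and HTC at 100 µM and 0.0986 for the doses of HTC, above the upper limits of 95% of the simulated values, 0.1001 and 0.0929. It was 0.0571 and 0.0210 for suvorexant with HTC at 100 µM and 10 µM, 0.0404 for suvorexant and imipramine and 0.0341 for imipramine and HTC at 10 µM, below the upper limits of 0.0918, 0.0958, 0.0978 and 0.0932. The 3 controls cannot be split into parts of 2 or more, so part of each covariance may come from the shared controls.

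Direct comparisons between treatments do not use the DMSO arrays. HTC at 100 µM differed from suvorexant in 4165 transcripts (1847 higher and 2318 lower) and from imipramine in 2614 (1280 higher and 1334 lower). HTC at 10 µM differed from suvorexant in 84 (77 higher and 7 lower), among them glulb, higher by 0.70 (adjusted p = 0.011), and hsd11b2, higher by 1.24 (adjusted p = 0.037). No transcript passed in limma between HTC at 10 µM and imipramine, where 3154 had an unadjusted p under 0.05. Residuals of these groups correlated by replicate number at 0.404, 0.436 and 0.244, above the limit of 0.1 set for pairing, and with the replicate number as a block, chosen after the data were seen, 0 passed in limma and 3797 had an unadjusted p under 0.05 (smallest adjusted p 0.068). Between imipramine and suvorexant 0 passed in limma and 1683 had an unadjusted p under 0.05. These counts do not show that the treatments acted alike. The fkbp5 transcript was higher by 4.39 at HTC 100 µM than with suvorexant (adjusted p = 0.00079), and stood 2.08 above imipramine without passing (adjusted p = 0.072), whereas hsd11b2 was higher by 2.13 than with imipramine (adjusted p = 8.9e-05).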

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

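The session, session 2, random slide and 3-array fits were chosen after the data were seen. The cause of each move below was not tested, except that fewer arrays or genes, a looser threshold or a fold minimum move counts by construction. The normexp offset of 50 and the floor of 16 likewise shrink log2 differences of dim genes by construction. A fixed slide leaves only replicate 1 of each HTC dose to inform its differences. Of the rule's 318 gene calls 148 ended when 1 array was left out and 306 with the slide fixed. In any planned setting but the fixed slide 176 ended, which includes those that ended when 1 array was left out. Of the 101 printed the numbers were 17, 91 and 25 in the same order, since stable calls were favoured in printing. Of 56 list calls 39 ended or turned when 1 array was left out, 36 in other settings, and 12 held everywhere but with an estimated correlation, which left 0 in each comparison. Arrays of the same number correlated in 16 of 30 pairs above 0.1, and 9 of 15 correlated best with their own number.

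Imipramine's count (17) became 59 with quantile normalization, 65 with normexp, 5 unfiltered, 41 with every probe, 68 with trend and robust, 104 with array weights, 35 with 2 groups alone, 75 with the replicate block, 187 at an adjusted p under 0.1, 139 with the session block, 11 with random slides, and 0 with the slide fixed, in session 2 or without the 3 arrays. At 10 µM (115) it became 190 with every probe, 11 with 2 groups, 197 with the replicate block, 196 under 0.1, 205 with the session block, and 0, 4 and 2 with the slide fixed, in session 2 and without the 3 arrays. At 100 µM (5789) it was 3670 with 2 groups, 99 with the slide fixed, 3459 at 1.5-fold and 3804 without the 3 arrays. Between doses (2683) it was 4890 with weights, 1296 with 2 groups, 0 with the slide fixed, 4506 under 0.1, 1687 at 1.5-fold, 1784 with random slides and 592 without the 3 arrays. In the F test (3444) it was 5203 with weights, 0 with the slide fixed, 1505 in session 2 and 1466 without the 3 arrays. The replicate block gave 0, 6739 and 3688 where numbers do not pair (suvorexant, 100 µM, between doses). In these comparisons it ended rho's call at 100 µM and changed no other printed gene call. Of the printed values not past the threshold, 2 passed with it for imipramine and 2 at 10 µM.

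With 1 array left out the transcripts ranged over 0 to 359 (imipramine), 29 to 122, 3644 to 5918, 1103 to 3160 and 1842 to 3711 (F), and the lists over 5 to 20 (suvorexant), 2 to 9, 11 to 14, 8 to 17 and 5 to 15. List counts became 3, 7 and 7 with quantile normalization (imipramine, 100 µM, between doses), 10 and 19 with the slide fixed (imipramine, 10 µM), and 2 without the 3 arrays (imipramine).

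Lists that turned, with adjusted p: slide fixed, imipramine lens 0.45, 10 µM sleep-wake 0.74, 100 µM photoreceptor 0.98 and liver and gut 0.00030, between doses liver and gut 4.6e-20, Nrf2 0.37, sterol 0.53, ribosomal 0.044 and mitochondrial 0.010. Others were ribosomal between doses 0.63 (quantile), mitochondrial at 10 µM 0.62 (session 2), liver and gut between doses 0.56 (without the 3 arrays), and for suvorexant proliferation 0.96 without DMSO replicate 1, and proteasome 0.94 and skeletal muscle markers 0.72 without suvorexant replicate 2 (ranges with 1 array left out 0.00018 to 0.96, 2.4e-08 to 0.94 and 5.04e-12 to 0.72). The log2 difference of hcrt turned to 0.040, 0.12, 0.22 and 0.13 for suvorexant (quantile, slide fixed, without DMSO replicate 2, without suvorexant replicate 3), 0.12 for imipramine (slide fixed), and 0.0020 and 0.015 at 100 µM (slide fixed, without DMSO replicate 2). That of slc6a4a turned to 0.070, 0.32, 0.015, 0.045 and 0.015 for imipramine (normexp, slide fixed, without imipramine replicate 1, session 2, without the 3 arrays) and 0.29 at 100 µM (slide fixed). With 1 array left out hcrt ranged over -0.21 to 0.22 for suvorexant and -0.41 to 0.015 at 100 µM, and slc6a4a over -0.20 to 0.015 for imipramine. Signal over background limits ugt5a1 and cyp8b1.3, dim in DMSO, and A_15_P567777, dim with imipramine. Of the 101 printed calls the log2 difference fell below 0.5 times its size for 26 with normexp, 5 with a floor of 16, 8 with the slide fixed and 0 with 1 array left out.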

Other observations

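The tests in this part on the lens and the shared DMSO arrays, the groupings within replicate numbers, and the choice of both gene families, were made only after the results were seen.

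Within the immunoproteasome and antigen processing genes, 11 of 12 measured fell at HTC 100 µM and none rose, with a median log2 difference of -1.44 against DMSO. Each of those 11 also fell after quantile normalization, normexp correction and in the deposited table, with medians of -1.39, -0.76 and -1.44. With the slide fixed none of the 12 passed, at a median of -1.01. Microglia markers had a median of -0.19 against DMSO, where that of all transcripts was -0.10, and did not pass the list test (adjusted p = 0.078). Against suvorexant and imipramine their medians were -0.306 and -0.214 (adjusted p = 0.0011 and 0.022, and 0.78 and 0.85 with an estimated correlation). Against HTC at 10 µM 8 of the 12 immunoproteasome and antigen processing genes fell. Besides irf1a, irf1b and the subunits named above, tap2a stood at -2.31, b2m at -1.29 and psme2 at -1.05, while b2ml stood at -0.08 and did not pass. Of 11 measured genes of the ugt5 family 4 rose and 1 fell at 100 µM and 4 rose at 10 µM. After normexp correction 3 rose and 1 fell at 100 µM and none passed at 10 µM, and with the slide fixed 2 rose at 100 µM and none passed at 10 µM. These genes are close in sequence and may cross-hybridise, which was not tested.

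The photoreceptor markers were higher at HTC 100 µM, which retina carried along with the brains could produce. A test written before its result set 12 genes of other retinal cells against them. Their difference of group means was -0.0344 (SE 0.0972), against 0.518 (SE 0.267) for the photoreceptor list, which met the condition set for excluding retina. The median of their log2 differences was 0.12, of the other sign. That condition was wrong, since all 12 transcripts were already well above background on every DMSO array, so that the brain's own signal would hide a small share of retina, and retina was left undecided after the result was seen. The median log2 difference of the 20 lens genes was -0.217 beside 0.600 for the photoreceptor list. The difference of group means of the per-array lens medians had an SE of 0.208. Of the 20, 17 were likewise above background on every DMSO array, so that whole eyes stay open too. With the slide fixed the photoreceptor list was not higher (adjusted p = 0.98), and in session 1 its median was -0.17.

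Uneven slides could enlarge the response at HTC 100 µM. Every group has 1 array in session 1 and 2 in session 2, so a constant shift between the sessions cannot alter a difference between groups. Of 1885 transcripts that differed between HTC 100 µM and imipramine in session 2, where their slides differ, 88.1% had the same sign on the slide that both share in session 1, beside 58.5% of all transcripts. With 1 array of HTC 100 µM on a shared slide this excludes nothing, and slide differences remain open as a cause.

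The glucocorticoid-responsive genes could appear higher because the shared DMSO arrays were low. At HTC 100 µM their median was 0.729 above suvorexant and 0.550 above imipramine, and 17 of 33 members were higher and 4 lower than with suvorexant, 11 and 2 than with imipramine. The list test passed at its preset correlation (adjusted p = 5.3e-06 and 8.9e-06) but not with an estimated one (adjusted p = 0.52 and 0.55). The group means of the per-array list medians differed by 0.764 (SE 0.102) from suvorexant and by 0.574 (SE 0.0466) from imipramine. These differences, which use no DMSO array, exclude low DMSO arrays as the whole cause. At HTC 10 µM the list's median was 0.0671 above suvorexant (adjusted p = 0.0014, and adjusted p = 0.67 with an estimated correlation) and 0.0238 above imipramine (adjusted p = 0.66, and adjusted p = 1.00 with an estimated correlation), as low DMSO arrays would give. The per-array medians differed there by 0.127 (SE 0.169) and 0.0836 (SE 0.0798), although hsd11b2 and glulb passed against suvorexant. Against DMSO the list was also higher with suvorexant and with imipramine. A response shared by the treatments would likewise give small differences between them, so this comparison cannot tell it from low DMSO arrays. Handling of pools that differed with the group, as with a visible effect of the dose, was not tested.

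Other splits of the 6 arrays of each comparison were tested, as planned. For suvorexant all 10 splits gave 0 transcripts, as the real one did. The real split alone (1 split) gave the most for imipramine (17, highest other 0, of 4 splits that exchange arrays only within a replicate number), HTC at 10 µM (115, highest other 0, of 4), HTC at 100 µM (5789, highest other 0, of 10) and the doses of HTC (2683, highest other 3, of 10), and so few splits cannot exclude chance. For the lists a split gave as many or more in 3 of 10 for suvorexant (15, highest other 20), 4 of 4 for imipramine (5, highest other 10), 4 of 4 for HTC at 10 µM (11, highest other 17), 6 of 10 for HTC at 100 µM (13, highest other 19) and 8 of 10 for the doses (12, highest other 16). The list counts were thus no larger than mixed groups give. Of 100 groupings of all 15 arrays only 1, the real one, reached 3444 transcripts in the F test, with 2172 as the highest other. Another 100 groupings exchanged arrays only within a replicate number, and so within a session. Again only 1, the real one, reached 3444, with 2179 as the highest other. Both sets exclude chance only if arrays of the same slide do not vary together. Replicates 2 and 3 of DMSO, imipramine and each HTC dose lie together on a slide, and the regroupings can part them. Variation between slides could therefore also place the real grouping highest, and it remains open.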
